A study of Homo sapiens with 12 samples.

How the data were processed

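RNA sequencing was done on 12 libraries of the human bronchial epithelial cell line BEAS-2B, grown per the labels' protocols in DMEM with fetal bovine serum and antibiotics. Total RNA was isolated with an RNeasy kit and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The 6 groups of 2 replicates were taken from the sample titles: cells never given nickel (UT), cells expanded from colonies after 6 weeks in 100 µM nickel chloride and over 6 months without it (NiW), and each of these after 3 weeks with nicotine at 1.25 or 2.5 µM (NTE1.25 and NTE2.5). The labels do not say whether one colony or several were used, whether UT cells were cloned, or whether replicates were separate cultures.

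The deposited table holds whole-number read counts per gene, not normalised. HISAT2, SAMtools, featureCounts and the build GRCh38 are named in the submitters' processing notes. Their versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart, and near-identical copies such as C4A and C4B or HLA-DRB1 and HLA-DRB5 can share reads. Such genes are named as uncertain in some places only, so a gene without that mark may share reads too. The table has 60666 genes by Ensembl identifier, of which 60650 have a symbol and 58420 a record in GENCODE release 29 (Ensembl 94), which served for coordinates on GRCh38 and gene types. Pseudogenes make up 15170 rows and took between 10.4% and 12.1% of the counts, and mitochondrial genes took between 3.88% and 5.33%. All deposited columns were used. Library totals ran from 29811637 to 74035104 counts, so that the floor of 3 counts lay between 0.041 and 0.1 CPM per library. Intervals of count ratios and floors cover counting error only, since the reads carry no molecular identifiers known here.

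Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM scaling (factors from 0.98 to 1.028), and the quasi-likelihood test in a model of the 6 groups over all 12 libraries with 6 residual degrees of freedom and a common biological coefficient of variation of 0.0434. The 21177 genes tested were called at a Benjamini-Hochberg adjusted p of 0.05 within each of 9 comparisons: NiW with UT, each nicotine group with its control, the interaction of background (NiW or UT) and nicotine at each dose, and the higher with the lower dose in each background. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM scaled by the TMM factors, as mean and SD, except for the genes that appear, the genes near 0 in UT that are compared as a percentage of NiW and the marker lists searched for other cell types, whose rules and values use CPM of the library totals. Where a group had 0 counts, folds are bounds against 3 counts over the group, and with 1 to 3 counts a ratio is given with an exact binomial 95% interval. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and a prior count of 2, and the p-values of the 29 lists were adjusted together by Benjamini-Hochberg within each comparison. The lists cover interferon-stimulated, interferon-gamma-induced, interferon signalling, nucleic acid sensing, antigen presentation, inflammatory, epithelial, mesenchymal, matrix, nicotinic, metal, hypoxia, NRF2, xenobiotic, stress response, p53, cell cycle, cholesterol, chromatin, respiratory chain, WNT, TGF-beta and Notch, mitochondrial RNA, ribosomal protein and histone genes, and markers of basal, secretory or ciliated, fibroblast, leukocyte and endothelial cells. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the figures.

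The groups, tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule names, per comparison, up to 6 rises and 6 falls with the largest log2 fold change (3 each for the dose comparisons) among called genes with a mean of at least 2 CPM and libraries that do not overlap between groups, leaving out pseudogenes, mitochondrial, Y-linked and unnamed genes. It adds up to 4 members with the smallest p from each list that camera called or that has 2 or more called members, 7 interferon genes because the series title names interferon signalling, ZEB1 and CDH1, and CHRNA5 and CHRNA7. The text names part of these, and a few genes that the rule names are not reported here. Of the genes tested 222 had no GENCODE record and could not be named, which affected 0 of the top places. Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, more than 1 CPM in at least 2 libraries, a replicate block, a fit of the compared groups alone, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were a GC correction (a spline with 4 degrees of freedom on transcript GC content, known for 98.8% of the genes tested), removal of pseudogene rows, removal of chromosome arm medians, and a minimum absolute log2 fold change of 1. Overlaps between comparisons with the same controls were set beside 20 simulations of unchanged groups. They were also recomputed with a separate control library for each comparison, from the fits that leave out 1 control library, in both ways, which was chosen after seeing the data. Chromosome arms were analysed where at least 20 protein-coding genes were measured, with 1000 shuffles, and in bins of 10 Mb with at least 5 genes, comparing odd with even bins over all arms. A test of bins in the most shifted arms alone, run first, was dropped because those arms had been picked for their shift. Genes that appear were also picked on 0.5 of the reads of each library and tested on the other reads at equal totals.

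The steps were tested on simulated data with 200 genes changed. These were drawn from genes with a mean of at least 2 CPM over all libraries, so recovery of lower genes was not tested. For NiW-NTE2.5 against NiW (20933 genes) 86.6% of changes of 0.5 on the log2 scale were recovered, 98.5% of changes of 1 and 100% of changes of 2, with 3 false calls. For UT-NTE2.5 against UT (20972 genes) the shares were 79.1%, 97% and 100%, with 1 false call, and for the interaction at the higher dose (20737 genes) 62.7%, 94% and 100%, with 8. A shift of 0.3 put into the interferon-stimulated list for NiW-NTE2.5 against NiW was found by camera with a Benjamini-Hochberg adjusted p of 1.1e-43 among 29 lists, and 0 lists that share no gene with it were called. Genes were drawn independently, so this does not test camera where the genes of a list vary together. A GC slope of 0.12 put into UT-NTE2.5 against UT (20977 genes) gave 633 calls before the GC correction and 0 after it, with a Spearman correlation to GC content of 0.77 before and 0.01 after.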

Results

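RNA sequencing counts were obtained from 12 libraries of BEAS-2B, an immortalised human bronchial epithelial cell line, in 6 groups of 2. UT cells had never been given nickel. NiW cells had spent 6 weeks in 100 µM nickel chloride, a salt of a carcinogenic metal, after which colonies were picked and grown without nickel for over 6 months. Both kinds of cell were left without nicotine, or received nicotine, the agonist of acetylcholine-gated ion channels, at 1.25 or 2.5 µM for 3 weeks (NTE1.25 and NTE2.5). The library totals were 29811637 and 51463522 counts in UT, 41397955 and 40840638 in UT-NTE1.25, 37235986 and 65120214 in UT-NTE2.5, 34306299 and 43461240 in NiW, 57720739 and 44177853 in NiW-NTE1.25, and 62647966 and 74035104 in NiW-NTE2.5. Replicates correlated across genes at r between 0.9983 and 0.9987, and differed by more than counting error, with a chi-square per degree of freedom between 2.84 and 6.09. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Levels are normalised read counts (CPM) as mean ± SD with n = 2, and log2 fold changes carry the standard error of the fit.

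The comparison of NiW with UT asks what still differs in cells grown out after nickel. Several genes without a count in UT were expressed in NiW. CADM3 (ENSG00000162706, chromosome 1, 159171609 to 159203313), which encodes a cell adhesion molecule, stood at 14.5 ± 1.8 CPM in NiW, at least 393-fold higher than in UT with a floor of 3 counts over the group. The forkhead factor FOXE1 was at least 150-fold higher, EYA2 had 0 counts in UT and 4.67 ± 0.12 CPM in NiW, the DNA repair enzyme MGMT was at least 119-fold higher and RCAN2 at least 114-fold. The tyrosine kinase SYK had 2 counts in UT and 17.1 ± 0.1 CPM in NiW, a ratio of 689 with an exact 95% counting interval of 190 to 5700. BCHE, which encodes butyrylcholinesterase, went the other way, from 16.7 ± 1.8 CPM to 3 counts, a ratio of 434 with an interval of 148 to 2100. SELENBP1 fell by 6.96 ± 0.24 on the log2 scale, TLL1 fell by 6.44 ± 0.34, M1AP fell by 5.04 ± 0.22 and DCDC2 fell by 4.25 ± 0.25. HIF1A-AS1 fell by 4.98 ± 0.27, but it is an antisense gene and the strand setting of the counting was not given, so this value is uncertain. In all, 10173 of 21177 genes tested passed edgeR's quasi-likelihood test at a Benjamini-Hochberg threshold of 0.05, with 5195 higher and 4978 lower, and 1456 and 577 of them by a log2 fold change of at least 1.

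Structural genes of both epithelial and mesenchymal kind were higher in NiW. Of 32 epithelial genes tested, 20 rose and 3 fell (21 and 3 adjusted over the list alone), among them the desmosome gene DSP by 2.56 ± 0.09 and the keratins KRT7 by 1.74 ± 0.05 and KRT17 by 1.56 ± 0.07. Of 34 genes of the epithelial-mesenchymal transition, 22 rose and 4 fell (23 and 4 over the list alone), with fibronectin FN1 at 3.00 ± 0.07 and NT5E at 2.18 ± 0.07. The repressor ZEB1 was higher by 1.41 ± 0.14, while E-cadherin CDH1 had a value of 0.89 ± 0.38 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.054). Among 34 matrix genes 23 rose and 7 fell, also over the list alone, with COL8A1 at 3.61 ± 0.09 and COL5A1 at 2.12 ± 0.06. Of 27 genes of the WNT, TGF-beta and Notch pathways 16 rose and 4 fell, also over the list alone, including the Notch target HES1 at 3.83 ± 0.15 and ID1 at 2.43 ± 0.09. The Benjamini-Hochberg adjusted p from limma's camera was 1.03e-05 for the epithelial list, 0.000121 for the mesenchymal, and 0.00231 for the matrix and for the pathway list. With an estimated correlation the adjusted p was 0.16, 0.16, 0.45 and 0.24, so none of these calls held. Markers of other cell types moved as well without their lists being called by camera, 3 of 7 endothelial markers higher and 1 lower (adjusted p = 0.429; VWF at 1.97 ± 0.44, ROBO4 at -1.23 ± 0.14), 3 of 7 leukocyte markers higher (0.173; CD14 at 0.67 ± 0.11), and 2 of 9 fibroblast markers higher and 2 lower (0.99; FBLN1 at 1.63 ± 0.09, LUM at -2.42 ± 0.38, COL1A1 at -0.61 ± 0.05). Of 15 mitochondrially encoded RNAs 8 were lower and 2 higher (0.124), with MT-RNR2 at -1.12 ± 0.05.

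The smaller lists called higher in NiW were nicotinic receptors and their modulators, basal airway markers, inflammatory genes and replication-type histones. Of 11 nicotinic genes 8 rose and 1 fell (8 and 2 over the list alone; camera adjusted p = 0.04), with LYPD1 at 4.57 ± 0.34, LYNX1 at 1.16 ± 0.14 and the receptor subunit CHRNA7 at 0.69 ± 0.11, while CHRNA5 at -0.33 ± 0.14 did not pass. CHRNA7 is uncertain, since reads can be shared with its partial copy CHRFAM7A, and it lies on the long arm of chromosome 15, where the median log2 fold change was 0.461. Of 6 basal markers 5 rose (5 over the list alone; camera adjusted p = 0.00231), with podoplanin PDPN at 4.77 ± 0.11 and KRT14 at 1.58 ± 0.35. Of 27 inflammatory genes 16 rose and 3 fell, also over the list alone (camera adjusted p = 0.0257), with IL6 at 1.22 ± 0.08 and IL1B at 1.12 ± 0.08. Histone genes, whose transcripts mostly lack poly(A) tails, rose in 7 of 14 cases and fell in 1, also over the list alone (camera adjusted p = 0.0371). With an estimated correlation the adjusted p was 0.45 for the nicotinic list, 0.24 for the basal, 0.4 for the inflammatory and 0.4 for the histone list.

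Ribosomal protein, respiratory chain and stress response genes were mostly lower in NiW. Of 59 ribosomal protein genes 50 fell and 4 rose, also over the list alone (camera adjusted p = 5.33e-12), with RPS6 at -1.09 ± 0.04. Of 39 respiratory chain genes 25 fell and 5 rose (26 and 5 over the list alone; camera adjusted p = 0.00231), such as ATP5MC1 at -0.38 ± 0.05. Of 29 genes of the unfolded protein and integrated stress responses 18 fell and 7 rose (18 and 8 over the list alone; camera adjusted p = 0.0257), including VLDLR at -1.63 ± 0.07 and PSAT1 at -1.08 ± 0.06. The adjusted p with an estimated correlation was 0.45 for each of these lists. RPS6 and VLDLR lie on the short arm of chromosome 9, whose protein-coding genes had a median log2 fold change of -0.673.

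The interferon-stimulated list was not shifted between NiW and UT. Of its 54 genes 8 rose, 19 fell and 27 did not pass, also over the list alone (camera adjusted p = 0.255, and 0.91 with an estimated correlation). RSAD2, an antiviral enzyme, rose by 3.65 ± 0.34 on the log2 scale, and CMPK2 had 3 counts in UT and 2.01 CPM in NiW, a ratio of 52.2 with an exact 95% counting interval of 17.5 to 256, whereas IFI27 fell by 4.12 ± 0.25 and IFITM1 by 1.49 ± 0.14. The interferon regulatory factor IRF7 fell by 1.09 ± 0.09 and the chemokine CXCL10 by 2.86 ± 0.29. Hypoxia genes split 11 higher and 14 lower of 37, and metal-response genes 5 higher and 6 lower of 16, with the zinc and manganese importer SLC39A8 up by 3.16 ± 0.12 and metallothionein MT1E down by 1.23 ± 0.10. Targets of NRF2, the oxidative stress factor, rose in 12 of 28 cases and fell in 4 (camera adjusted p = 0.0957), with NQO1 at 1.44 ± 0.05. Of 17 xenobiotic genes 10 rose and 3 fell (camera adjusted p = 0.0756), with GSTM1 at -2.20 ± 0.11. Over the list alone the splits were 11 and 16 for hypoxia and the same as given for the metal, NRF2 and xenobiotic lists. Of 39 chromatin regulators 8 rose and 8 fell (7 and 8 over the list alone; camera adjusted p = 0.99), including TET1 at -1.42 ± 0.15.

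Chromosome arms shifted as blocks between NiW and UT. Over protein-coding genes the median log2 fold change was -0.673 on 9p, -0.381 on 20p, -0.377 on 18p and -0.361 on 17p, against 0.466 on 7p, 0.461 on 15q, 0.391 on 13q, 0.361 on 5p and 0.341 on 20q. After the median of each arm was removed, 7664 of the 10173 calls were kept (75.3%).

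**Figure D1:**
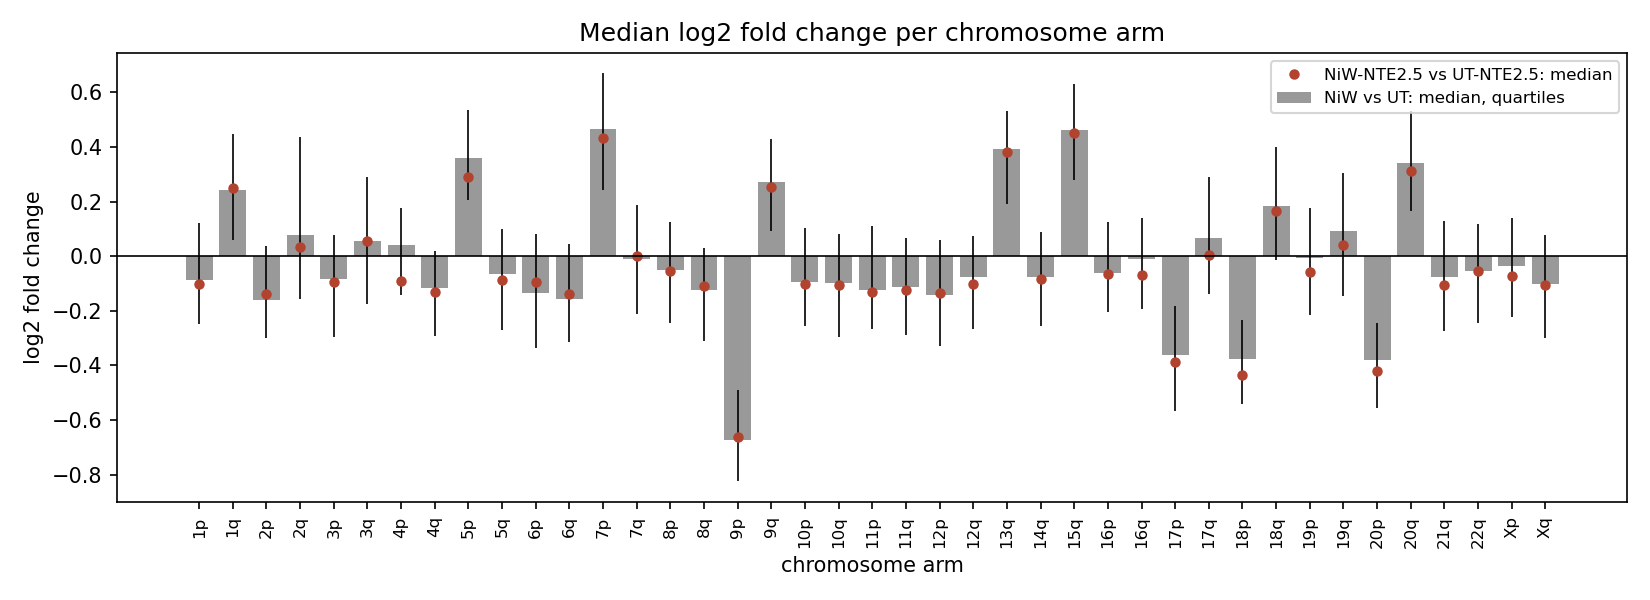
Bars give the median log2 fold change of protein-coding genes on each chromosome arm for NiW against UT, with lines over the quartiles, and points give the same median for NiW-NTE2.5 against UT-NTE2.5. The bar of 9p reaches -0.673 and that of 7p 0.466, and the points lie close to the bars.

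The lower nicotine dose was compared with no nicotine in cells without nickel history. HES1, a transcriptional repressor of the Notch pathway, rose 4.22-fold, from 1.18 ± 0.19 to 5.13 ± 0.57 CPM, and PDPN rose 3.69-fold, from 1.1 ± 0.11 to 4.13 ± 0.065 CPM. PPM1L, FOSB, PCDHB5 and ENDOD1 rose between 3.52-fold and 3.67-fold, the immediate early gene FOSB with a wide spread, 13.2 ± 5.5 CPM after nicotine. Among falls, MYPN was 1.78-fold lower, the death ligand TNFSF10 1.77-fold, TXNIP, an inhibitor of thioredoxin, 1.66-fold and NDRG1 1.63-fold. HSPA1L was 1.55-fold lower and the complement gene C4A 1.53-fold, the latter uncertain because C4B is a near-identical copy. In all, 416 genes were higher and 119 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 535 together, and the count was 302 without UT replicate 1, 222 without UT replicate 2 and 298 without UT-NTE1.25 replicate 2.

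Of 37 hypoxia-responsive genes 10 fell and none rose at the lower dose in UT (11 over the list alone; camera adjusted p = 1.92e-08), with ANGPTL4 at -2.01 ± 0.25, DDIT4 at -0.52 ± 0.08 and BNIP3 at -0.38 ± 0.05. The adjusted p was 0.21 with an estimated correlation. Of 15 mitochondrially encoded RNAs 7 fell (9 over the list alone; camera adjusted p = 2.56e-06, and 0.47 with an estimated correlation), with MT-RNR2 at -0.46 ± 0.05. The share of all counts in mitochondrial genes was 4.57% and 3.88% in the UT-NTE1.25 libraries, against 4.8% and 4.78% in UT. Inflammatory genes rose in 7 of 27 cases (12 and 1 lower over the list alone; camera adjusted p = 0.0018, and 0.31 with an estimated correlation), among them the chemokines CCL2 at 0.42 ± 0.04 and CXCL8 at 0.25 ± 0.05. Antigen presentation genes rose in 4 of 28 cases (7 over the list alone; camera adjusted p = 0.0122), with HLA-B at 0.19 ± 0.04 and HLA-F at 0.25 ± 0.06. With an estimated correlation the adjusted p was 0.47, and without UT-NTE1.25 replicate 2 the camera value was 0.056. Of the 54 interferon-stimulated genes 1 rose and 2 fell (3 and 4 over the list alone; camera adjusted p = 0.0855, and 0.74 with an estimated correlation), and without UT-NTE1.25 replicate 1 the camera adjusted p was 0.018, in the lower direction. Matrix genes rose in 6 of 34 cases, p53 targets in 3 of 24, cholesterol genes in 2 of 26, nicotinic genes in 1 of 11, and the chromatin gene KDM3A alone of 39 fell, by 0.24 ± 0.05. Over the list alone these counts were 6, 4, 3, 1 and 1. The adjusted p from camera for them was 0.00289, 0.034, 0.00453, 0.00682 and 0.0263, and with an estimated correlation 0.49, 0.39, 0.47, 0.47 and 0.49.

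The higher dose moved many more genes in UT. ROBO1 (ENSG00000169855, chromosome 3, 78597240 to 79767815), an axon guidance receptor, rose 128-fold, from 0.103 ± 0.049 to 14.8 ± 1.3 CPM, and stood at 28.2 ± 2.4 CPM in NiW without nicotine. The oxysterol hydroxylase CYP7B1 rose 61.7-fold, TMTC2 52.7-fold, KLHL13 25.1-fold, GALNT14 19.1-fold and GAS1 17.1-fold, each from a level between 0.0776 CPM for CYP7B1 and 0.38 CPM for GALNT14. Among falls, the decoy receptor TNFRSF11B was 2.69-fold lower, IGFBP3 2.37-fold, the deiodinase DIO2 2.25-fold and DKK1, a secreted WNT inhibitor, 2.16-fold, from 389 ± 7.2 to 180 ± 8.9 CPM. FGF1 was 1.83-fold lower and PSG1 1.82-fold, the latter one of a family of similar copies and so uncertain. By edgeR's quasi-likelihood test 2818 genes were higher and 1988 lower at a Benjamini-Hochberg threshold of 0.05, 4806 together, and the count was 2194 without UT replicate 2 and 2861 without UT-NTE2.5 replicate 1. Fold changes correlated across genes with GC content (Spearman 0.473), and 3377 of the calls (70.3%) were kept after a correction for GC content, which turned the balance to 2063 higher and 3255 lower.

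Cholesterol genes rose nearly throughout at the higher dose in UT. Of 26 genes of sterol synthesis and uptake 22 rose and none fell (23 over the list alone; camera adjusted p = 3.42e-13), with the feedback regulator INSIG1 at 1.34 ± 0.07 and the synthase HMGCS1 at 1.20 ± 0.07. The adjusted p was 0.12 with an estimated correlation. Of 54 interferon-stimulated genes 27 rose and 1 fell (30 and 1 over the list alone; camera adjusted p = 2.84e-07), with RSAD2 at 3.52 ± 0.34, IFI44 at 1.58 ± 0.15 and OAS3 at 0.46 ± 0.05. With an estimated correlation the adjusted p was 0.27. Of 28 antigen presentation genes 16 rose, also over the list alone (camera adjusted p = 6.58e-07, and 0.22 with an estimated correlation), with HLA-DPA1 at 3.55 ± 0.22 and HLA-B at 0.53 ± 0.04. HLA-DRB1 rose by 5.32 ± 0.34 and is uncertain, because reads can be shared with HLA-DRB5. Interferon-gamma-induced genes rose in 13 of 32 cases and fell in 3 (15 and 4 over the list alone; camera adjusted p = 0.0314, and 0.55 with an estimated correlation), with the guanylate-binding protein GBP4 at 2.16 ± 0.14.

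Matrix genes rose in 18 of 34 cases and fell in 1, with the laminin gene LAMA5 higher by 1.58 ± 0.12. The p53 targets rose in 10 of 24 cases, such as BTG2 by 1.22 ± 0.08 and the cell cycle inhibitor CDKN1A by 0.62 ± 0.05. Nicotinic genes rose in 5 of 11 cases and fell in 1, with LYNX1 higher by 1.23 ± 0.13. Over the list alone the counts were the same except for 6 nicotinic genes higher. The camera adjusted p was 1.41e-05, 4.26e-05 and 0.000837, and with an estimated correlation 0.27, 0.12 and 0.27. Inflammatory genes rose in 11 of 27 cases and fell in 2 (13 and 3 over the list alone; camera adjusted p = 0.0141, and 0.27 with an estimated correlation), with CXCL2 at 0.72 ± 0.07 and IL6 at 0.57 ± 0.08. Pathway genes rose in 11 of 27 and fell in 3, also over the list alone (camera adjusted p = 0.0467, and 0.27 with an estimated correlation), with HES1 at 3.28 ± 0.15. Ribosomal protein genes fell in 24 of 59 cases, also over the list alone (camera adjusted p = 4.35e-06, and 0.55 with an estimated correlation), and respiratory chain genes fell in 8 of 39 and rose in 2 (8 and 3 over the list alone; camera adjusted p = 0.0314, and 0.55 with an estimated correlation). Markers of other cell types moved with this dose. Of 9 fibroblast markers 4 rose (5 over the list alone; camera adjusted p = 0.0141), of 7 leukocyte markers 4 (4 over the list alone; 0.0184) and of 6 basal markers 3 (3 over the list alone; 0.0288), with an adjusted p of 0.27, 0.22 and 0.27 with an estimated correlation. The most abundant fibroblast marker was COL1A1 at 2670 CPM, against 2140 in UT, and the most abundant leukocyte marker CD14 at 6.7 CPM, against 7.78 in UT. Of 7 secretory and ciliated markers 2 rose (3 over the list alone; camera adjusted p = 0.299, and 0.55 with an estimated correlation), and of 7 endothelial markers 1 rose and 1 fell, also over the list alone (0.446, and 0.73 with an estimated correlation).

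At the lower dose in NiW the growth factor FGF5 was 2.55-fold lower, the immediate early genes FOSB 2.35-fold, FOS 2.1-fold and EGR1 1.89-fold, the phosphatase DUSP6 1.95-fold and the kinase SGK1 1.92-fold. The NiW libraries themselves were spread widely for FOS (114 ± 48 CPM) and FOSB (58.8 ± 26 CPM). The lipid-presenting molecule CD1D rose 2.75-fold, EPDR1 2.37-fold, HMGN5 2.32-fold, DPYSL3 2.31-fold, KIAA0040 2.22-fold and the scavenger receptor COLEC12 2.16-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 229 genes were higher and 235 lower, 464 together. The count was 180 without NiW replicate 1, 212 without NiW replicate 2 and 218 without NiW-NTE1.25 replicate 1.

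Hypoxia genes fell in NiW at the lower dose, 12 of 37 with none higher (19 over the list alone; camera adjusted p = 8.05e-16), with STC2 at -0.81 ± 0.05, NDRG1 at -0.53 ± 0.06 and BNIP3 at -0.43 ± 0.05. This was the 1 list call of all 9 comparisons that held with an estimated correlation (adjusted p = 0.047). Mitochondrially encoded RNAs fell in 9 of 15 cases (14 over the list alone; camera adjusted p = 2.04e-07, and 0.43 with an estimated correlation), and the share of counts in mitochondrial genes was 3.96% and 4.06%, against 4.7% and 4.41% in NiW. Antigen presentation genes rose in 6 of 28 cases (15 over the list alone; camera adjusted p = 6.86e-12, and 0.12 with an estimated correlation), with HLA-DQB1 at 2.98 ± 0.55, HLA-DMB at 1.60 ± 0.37 and HLA-F at 0.28 ± 0.06. Interferon-stimulated genes rose in 6 of 54 cases (10 and 1 lower over the list alone; camera adjusted p = 1.32e-06, and 0.43 with an estimated correlation), including the antiviral sensor OAS1 at 0.55 ± 0.12, TRIM22 at 0.51 ± 0.09 and BST2 at 0.47 ± 0.12. Mesenchymal genes fell in 10 of 34 cases (11 over the list alone; camera adjusted p = 0.00112, and 0.21 with an estimated correlation), among them VIM at -0.29 ± 0.04. Cholesterol genes rose in 2 of 26 cases, among them INSIG1 at 0.47 ± 0.07 (6 over the list alone; camera adjusted p = 9.1e-06, and 0.31 with an estimated correlation). Interferon-gamma-induced genes rose in 3 of 32 cases and fell in 1 (7 and 1 over the list alone; camera adjusted p = 0.00563, and 0.46 with an estimated correlation), and STAT2 at 0.24 ± 0.06 was the 1 signalling gene of 20 that rose (1 over the list alone; camera adjusted p = 0.0311, and 0.24 with an estimated correlation). NRF2 targets fell in 4 of 28 cases and rose in 1, also over the list alone (camera adjusted p = 0.0118, and 0.46 with an estimated correlation), and stress response genes fell in 4 of 29 (6 over the list alone; camera adjusted p = 0.0465, and 0.5 with an estimated correlation), with ATF3 at -0.68 ± 0.09. The nicotinic list was called higher and the ribosomal list lower (camera adjusted p = 0.0148 and 0.00124, and 0.44 and 0.66 with an estimated correlation) with 0 members past edgeR's test, also over the list alone, where 4 of 11 and 7 of 59 had an unadjusted p under 0.05 and DESeq2 called 0 and 1.

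The higher dose in NiW gave more calls than any other comparison of nicotine with its control. Its libraries held 62647966 and 74035104 counts, against 37235986 and 65120214 in UT-NTE2.5, and whether depth added calls was not tested. ITM2A rose 17-fold, from 0.506 ± 0.042 to 8.69 ± 0.38 CPM, MAN1A1 12.7-fold, the galactosyltransferase UGT8 11.1-fold, GNAO1 8.66-fold and TMSB15A 8.35-fold. HLA-DRB5 rose 9.35-fold and is uncertain for the reason given for HLA-DRB1. The collagenase MMP1 was 5.01-fold lower, FGF5 3.88-fold, C4BPB 3.44-fold, the BMP antagonist NOG 3.25-fold, the transcription factor SNAI2 3-fold, and DKK1 3-fold, from 473 ± 31 to 158 ± 17 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3310 genes were higher and 3216 lower, 6526 together. The count was 3967 without NiW-NTE2.5 replicate 2, and 5833 calls (89.4%) were kept after a correction for GC content, with 3027 genes higher and 4157 lower.

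Antigen presentation genes rose almost without exception in NiW at the higher dose, 27 of 28 (28 over the list alone; camera adjusted p = 5.86e-16, and 0.12 with an estimated correlation), with HLA-F at 0.81 ± 0.06 and HLA-B at 0.76 ± 0.04. Of 54 interferon-stimulated genes 35 rose and none fell, also over the list alone (camera adjusted p = 2.36e-09, and 0.29 with an estimated correlation), with OAS1 at 1.18 ± 0.12, BST2 at 1.16 ± 0.11 and MX2 at 1.07 ± 0.10. Interferon-gamma-induced genes rose in 19 of 32 cases and fell in 3, also over the list alone (camera adjusted p = 4e-05, and 0.29 with an estimated correlation), with the complement proteases C1R at 1.20 ± 0.06 and C1S at 0.99 ± 0.06. Of 20 genes of the interferon signalling chain 5 rose and 2 fell, also over the list alone (camera adjusted p = 0.0796, and 0.29 with an estimated correlation), with STAT2 at 0.59 ± 0.06 and IRF7 at 0.53 ± 0.09. Of 18 nucleic acid sensors 6 rose, also over the list alone (camera adjusted p = 0.229, and 0.38 with an estimated correlation), such as DHX58 at 0.64 ± 0.09.

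Cell cycle genes fell in 21 of 42 cases and rose in 1 in NiW at the higher dose, also over the list alone (camera adjusted p = 0.00164, and 0.29 with an estimated correlation), with AURKA at -0.48 ± 0.05 and CDC20 at -0.33 ± 0.04. Inflammatory genes fell in 9 of 27 cases and rose in 5, also over the list alone (camera adjusted p = 0.0457, and 0.29 with an estimated correlation), with IL11 at -1.10 ± 0.09 and CXCL8 at -0.92 ± 0.05. Matrix genes rose in 19 of 34 cases and fell in 3 (20 and 4 over the list alone; camera adjusted p = 0.00231, and 0.38 with an estimated correlation), with LAMA5 at 1.32 ± 0.09 and THBS1 at -1.06 ± 0.07. Cholesterol genes rose in 15 of 26 cases and fell in 2, also over the list alone (camera adjusted p = 0.00169, and 0.32 with an estimated correlation), with INSIG1 at 0.52 ± 0.07. Epithelial genes rose in 13 of 32 cases and fell in 5 (14 and 5 over the list alone; camera adjusted p = 0.0268, and 0.29 with an estimated correlation), KRT7 among the lower ones with 278 ± 14 CPM against 556 ± 43. The mesenchymal list was not called (camera adjusted p = 0.339), although VIM fell by 0.75 ± 0.04 and CD44 by 0.90 ± 0.06. Of 9 fibroblast markers 2 rose (4 over the list alone; camera adjusted p = 0.0393) and of 7 leukocyte markers 3 (3 over the list alone; 0.0473), each with an adjusted p of 0.29 with an estimated correlation. COL1A1 stood at 1740 CPM against 1400 in NiW, and CD14 at 19 against 12.5. The other marker lists were not called. Of 7 secretory and ciliated markers 3 rose, also over the list alone (camera adjusted p = 0.0796, and 0.36 with an estimated correlation). Of 6 basal markers 3 rose and 1 fell (4 and 1 over the list alone; 0.0861, and 0.37). Of 7 endothelial markers 2 fell, also over the list alone (0.145, and 0.39). Nicotinic genes rose in 5 of 11 cases and fell in 1, also over the list alone, with the subunits CHRNB1 at 0.75 ± 0.06 and CHRNA5 at 0.56 ± 0.13, p53 targets rose in 7 of 24 and fell in 2 (9 and 2 over the list alone), with BTG2 at 0.71 ± 0.08, and ribosomal protein genes fell in 11 of 59 and rose in 2 (9 and 2 over the list alone). The camera adjusted p was 0.0283 for each of these 3 lists, and 0.38, 0.29 and 0.75 with an estimated correlation.

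**Figure D2:**
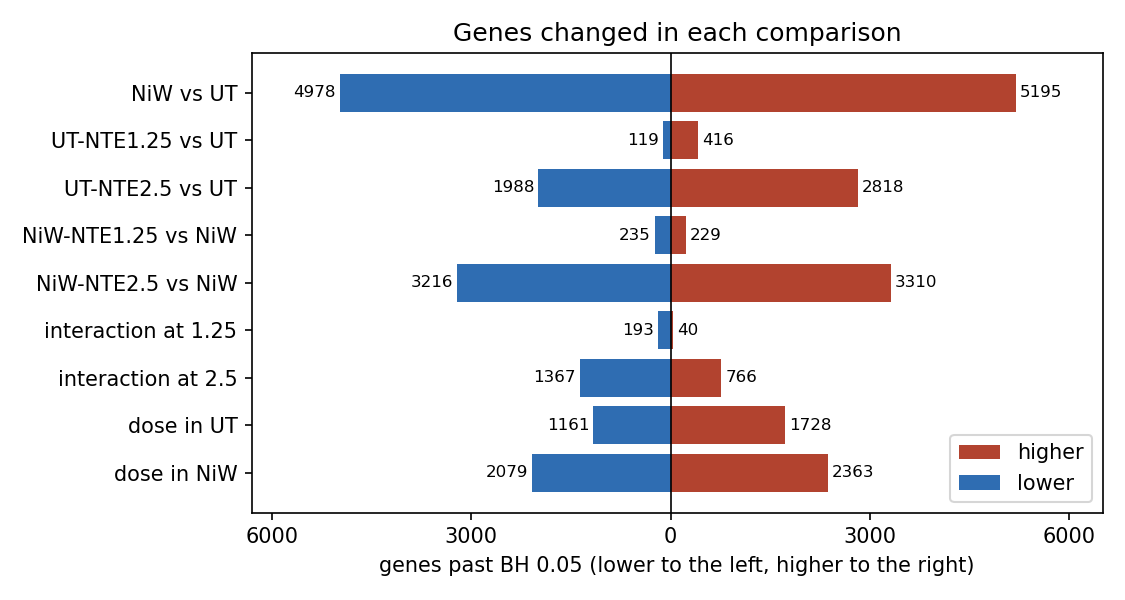
Bars give the number of genes past a Benjamini-Hochberg threshold of 0.05 in each comparison, higher to the right and lower to the left of 0. NiW against UT has 5195 and 4978, and the higher nicotine dose has 2818 and 1988 in UT and 3310 and 3216 in NiW. After a correction for GC content these are 4824 and 5865, 2063 and 3255, and 3027 and 4157, so which direction has more genes depends on that correction. In NiW it also depends on the tool, with 2478 higher and 2839 lower by DESeq2. Among calls of at least 2-fold at the higher dose 784 were higher and 60 lower in UT, and 680 and 145 in NiW, and after the correction 691 and 74, and 608 and 171.

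The series title names interferon signalling, and 6 genes of it that had been chosen beforehand are given here. At the higher dose OAS1 rose by 0.76 ± 0.11 in UT and 1.18 ± 0.12 in NiW, MX1 by 0.49 ± 0.09 and 0.91 ± 0.09, ISG15 by 0.46 ± 0.07 and 0.35 ± 0.07, and IFIT1 by 0.28 ± 0.10 and 0.39 ± 0.11. IRF7 had 0.19 ± 0.08 in UT, which did not pass, and rose by 0.53 ± 0.09 in NiW. IRF9 had 0.15 ± 0.25 in UT and 0.21 ± 0.25 in NiW, neither of which passed. At the lower dose 1 of these 6 genes passed, OAS1 in NiW at 0.55 ± 0.12.

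**Figure D3:**
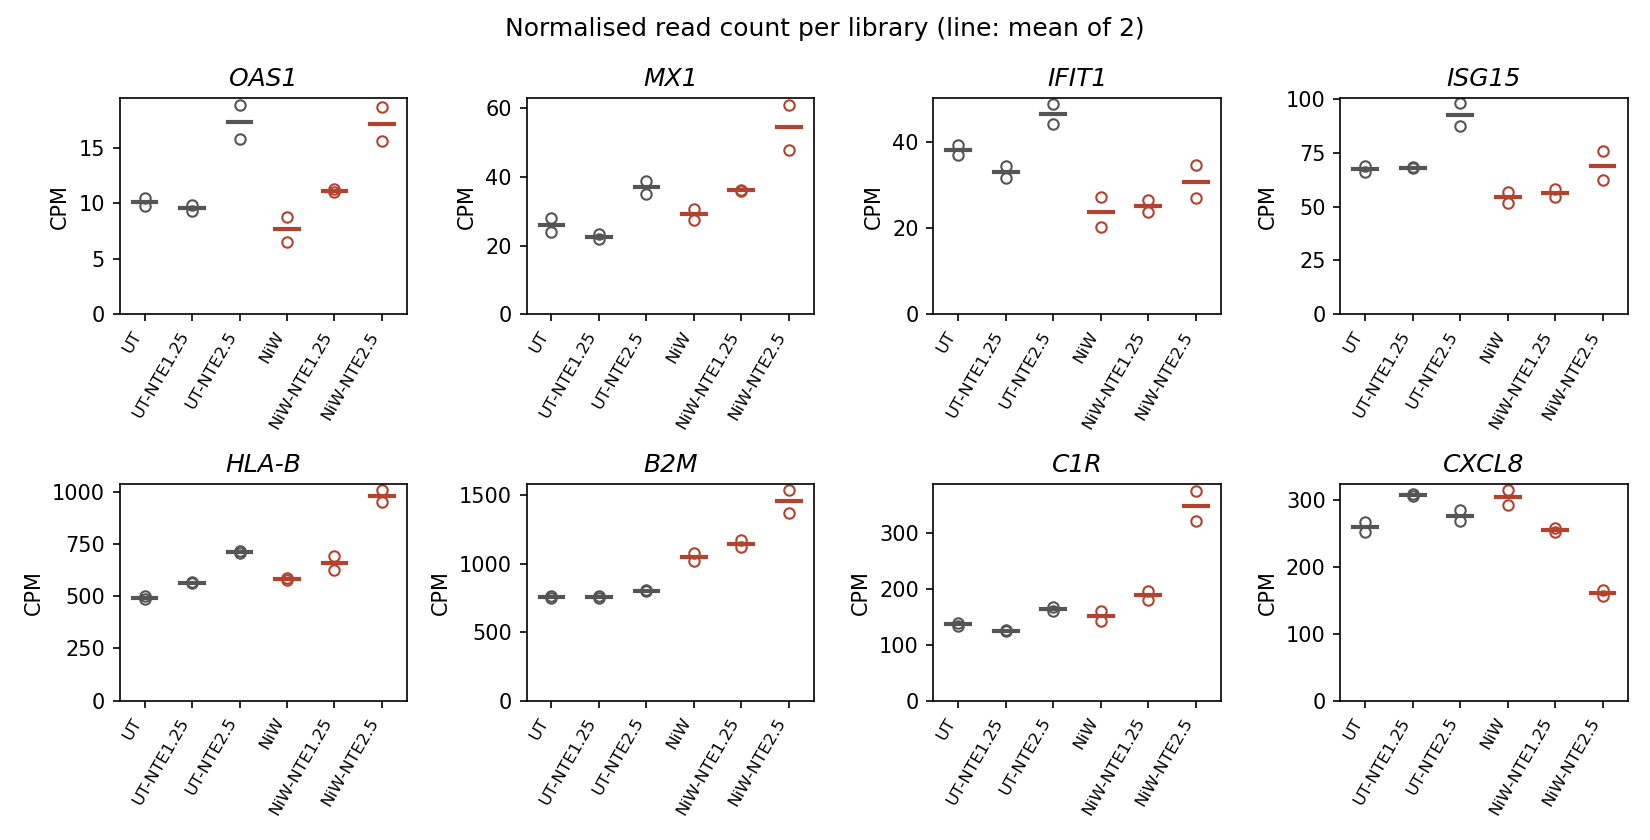
Normalised read counts (CPM) of 8 genes in the 6 groups, with a circle per library and a line at the mean of the 2 libraries, UT groups in grey and NiW groups in red. OAS1 and MX1 rise with the higher dose in both backgrounds, with log2 fold changes of 0.76 and 0.49 in UT and 1.18 and 0.91 in NiW, and CXCL8 has a log2 fold change of -0.92 in NiW.

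Whether the response to nicotine differed between NiW and UT was tested as an interaction, the log2 fold change in NiW minus that in UT. NiW cells had been given nickel, picked as colonies and grown for over 6 months. The design cannot tell these apart as the source of a difference. At the higher dose the inflammatory genes parted, 14 of 27 with a lower and 1 with a higher response in NiW (16 and 1 over the list alone; camera adjusted p = 7.85e-06, and 0.18 with an estimated correlation). The neutrophil chemokines CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) and CXCL1 differed by -1.01 ± 0.07 and -0.91 ± 0.08. Of 26 cholesterol genes 13 responded less and none more in NiW (16 over the list alone; camera adjusted p = 7.85e-06, and 0.43 with an estimated correlation), with HMGCS1 at -0.94 ± 0.10. Antigen presentation genes responded more in NiW in 8 of 28 cases and less in 2 (12 and 2 over the list alone; camera adjusted p = 8.2e-06, and 0.43 with an estimated correlation), with PSMB9 at 0.43 ± 0.08 and B2M, the invariant chain of class I molecules, at 0.38 ± 0.06. Interferon-gamma-induced genes responded more in 8 of 32 cases and less in 1 (8 and 3 over the list alone; camera adjusted p = 0.0218, and 0.7 with an estimated correlation), with C1R at 0.93 ± 0.08 against GBP4 at -1.53 ± 0.19. Cell cycle genes were lower in 15 of 42 cases and higher in 4 (18 and 6 over the list alone; camera adjusted p = 0.0107, and 0.43 with an estimated correlation), with CDCA8 at -0.51 ± 0.06 and PLK1 at -0.47 ± 0.07. Of 7 endothelial markers VWF at -2.66 ± 0.64 and TIE1 at -1.64 ± 0.53 were lower (3 over the list alone; camera adjusted p = 0.02, and 0.43 with an estimated correlation). VWF was low throughout, at 0.22 ± 0.023 CPM in UT, 0.371 ± 0.24 in UT-NTE2.5, 0.876 ± 0.14 in NiW and 0.207 ± 0.014 in NiW-NTE2.5.

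The interferon-stimulated list did not pass the interaction test at the higher dose (camera adjusted p = 0.123, and 0.9 with an estimated correlation). Of its 54 genes 7 responded more and 3 less in NiW (15 and 7 over the list alone), the median difference being 0.11 and the mean -0.00. MX1 differed by 0.42 ± 0.13 and IFITM1 by 0.87 ± 0.18, whereas RSAD2 differed by -2.61 ± 0.41, IFI44 by -1.11 ± 0.20 and OAS3 by -0.27 ± 0.07. The camera adjusted p for the list was 0.0038 without NiW-NTE2.5 replicate 1, 0.021 without NiW replicate 1 and 0.048 without UT-NTE2.5 replicate 1.

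Among the largest differences at the higher dose were genes near 0 in UT that rose there with nicotine and were already expressed in NiW. ROBO1 differed by -6.95 ± 0.24, LRCH2 by -5.30 ± 0.38, TMTC2 by -5.21 ± 0.31 and SLC9A9 by -4.96 ± 0.46. CADM3 and ZNF804A had fitted values of -8.32 ± 0.82 and -5.46 ± 0.63, which depend on the prior count because both lay under the floor of 3 counts in UT. In CPM, CADM3 was higher with nicotine in NiW too, at 14.5 in NiW, 24 in NiW-NTE1.25 and 33.3 in NiW-NTE2.5. It stood at 0 in UT, 0.356 in UT-NTE1.25 and 1.88 in UT-NTE2.5. TMSB15A differed by 2.56 ± 0.36, COLEC12 by 2.07 ± 0.34, the retinaldehyde reductase DHRS3 by 2.01 ± 0.21, PCLO by 1.98 ± 0.27, GNG4 by 1.67 ± 0.21 and ANGPTL4 by 1.48 ± 0.30. In all 766 genes responded more and 1367 less in NiW by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2133 together. The count was 1132 without UT replicate 2, 1312 without NiW replicate 2 and 1176 without NiW-NTE2.5 replicate 2.

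**Figure D4:**
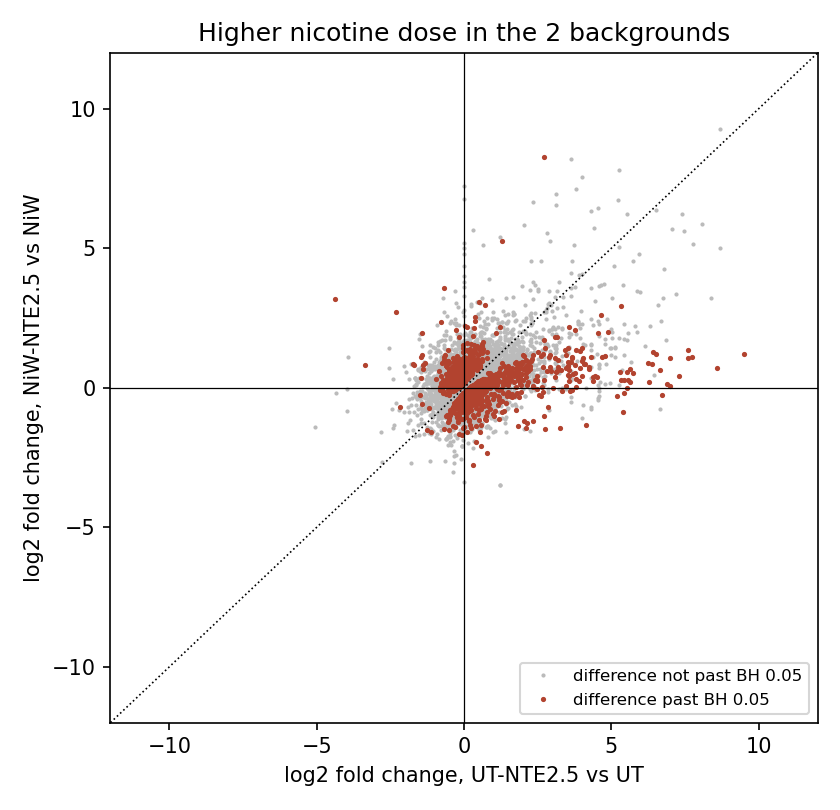
Each point is a gene, with its log2 fold change at the higher dose in UT on the x axis and in NiW on the y axis, red where the 2 differ past a Benjamini-Hochberg threshold of 0.05. The dotted line marks equal change, and 1556 genes were higher in both backgrounds against 169 with opposite calls.

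At the lower dose 40 genes responded more and 193 less in NiW by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 233 together. CCN2, a matricellular growth factor, differed by -1.28 ± 0.12, FOSB by -3.10 ± 0.47, TMTC2 by -3.32 ± 0.38, ROBO1 by -3.24 ± 0.39 and CELF2 by -3.12 ± 0.52. DHRS3 differed by 1.34 ± 0.23, DPYSL3 by 1.03 ± 0.19, TNFSF10 by 0.94 ± 0.23 and GJA1 by 0.91 ± 0.18, and the copies C4B and C4A, which share reads, by 1.06 ± 0.21 and 1.04 ± 0.21. CADM3 and ZNF804A had fitted values of -6.40 ± 1.22 and -4.05 ± 0.77, again set by the prior count. The list of 54 interferon-stimulated genes was called higher by camera (adjusted p = 6.56e-07) with 0 members past edgeR's test over all genes and 6 over the list alone, and the adjusted p was 0.7 with an estimated correlation. An unadjusted p under 0.05 was found for 21 of them, and DESeq2 called 2. Of the interferon-gamma-induced genes 3 of 32 were higher (4 and 1 lower over the list alone), C1S at 0.47 ± 0.09, C1R at 0.44 ± 0.09 and TNFSF10, and of the signalling genes STAT2 alone of 20, at 0.38 ± 0.09 (1 over the list alone). Of 28 antigen presentation genes 0 passed edgeR's test, also over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 0. Of 34 mesenchymal genes 5 were lower and 1 higher (13 and 3 over the list alone). The camera adjusted p was 0.0336, 0.0311, 0.0138 and 0.00115 for these 4 lists, and with an estimated correlation 0.7, 0.3, 0.7 and 0.3. The count of 233 was 126 without UT replicate 1, 84 without UT replicate 2, 140 without UT-NTE1.25 replicate 2, 155 without NiW replicate 1 and 143 without NiW replicate 2, and the antigen presentation call was lost without any of UT replicate 1, UT replicate 2, UT-NTE1.25 replicate 1, NiW replicate 2 and NiW-NTE1.25 replicate 1 (camera adjusted p = 0.1, 0.092, 0.13, 0.12 and 0.12).

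Setting the doses against each other avoids the shared control. In UT, the higher dose had 1728 genes higher and 1161 lower than the lower dose, 2889 together, including ROBO1 at 3.65 ± 0.13, HLA-DRB1 at 2.49 ± 0.22, ITM2A at 2.36 ± 0.20, TNFRSF11B at -1.18 ± 0.07, IGFBP3 at -1.17 ± 0.05 and DIO2 at -1.15 ± 0.06. In NiW 2363 were higher and 2079 lower, 4442 together, including GNAO1 at 2.08 ± 0.22, ITM2A at 2.07 ± 0.14, MAN1A1 at 1.65 ± 0.23, MMP1 at -2.02 ± 0.23, COL5A3 at -1.39 ± 0.14 and the cytokine CSF2 at -1.29 ± 0.16. Interferon-stimulated genes were higher at the higher dose in 30 of 54 cases in UT and 28 in NiW with none lower (34 higher, and 31 higher with 1 lower, over the list alone; camera adjusted p = 4.49e-14 and 1.07e-06, and 0.22 and 0.37 with an estimated correlation). Hypoxia genes, lower at the lower dose, were higher at the higher dose than at the lower in 18 of 37 cases in UT and 23 in NiW, with 4 and 3 lower (23 and 24 higher, 4 and 5 lower, over the list alone; camera adjusted p = 1.15e-05 and 1.46e-07, and 0.22 and 0.15 with an estimated correlation). The higher dose against its own control was not called for this list, with 11 higher and 5 lower in UT and 10 and 9 in NiW (11 and 5, and 11 and 9, over the list alone; camera adjusted p = 0.76 and 0.724, and 0.9 and 0.89 with an estimated correlation). Both the fall at the lower dose and the rise between the doses use the NTE1.25 libraries, so a shift in those alone would give both. Mitochondrially encoded RNAs were also higher in 14 of 15 cases in UT and 9 in NiW (15 and 11 over the list alone; camera adjusted p = 8.3e-08 and 0.000623, and 0.29 and 0.5 with an estimated correlation). Basal airway markers were higher in 3 of 6 cases in UT, and 2 were higher and 1 lower in NiW (3 higher and 1 lower in each over the list alone; camera adjusted p = 0.0198 and 0.104, and 0.29 and 0.38 with an estimated correlation). Fibroblast markers were higher in 3 of 9 cases in each background (4 and 3 over the list alone; camera adjusted p = 0.0341 and 0.0894, and 0.29 and 0.37 with an estimated correlation). More genes higher than lower was not kept after a correction for GC content, with 1399 higher and 2149 lower in UT and 2125 and 2976 in NiW, and DESeq2 gave 1245 and 1236 in UT and 1686 and 1878 in NiW. Without UT-NTE1.25 replicate 1, UT-NTE1.25 replicate 2 or UT-NTE2.5 replicate 1 the count in UT was 1443, 1754 and 1468. Without NiW-NTE1.25 replicate 2 or NiW-NTE2.5 replicate 2 the count in NiW was 2743 and 2034.

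Responses in the 2 backgrounds, which share no library, overlapped. At the higher dose log2 fold changes correlated across genes at r = 0.471 (Spearman 0.381), 1556 genes were higher in both against 440 for independent lists, 935 were lower in both against 302, and 169 had opposite calls against 739. At the lower dose r was 0.228 (Spearman 0.155), with 82 higher in both against 4.5, 25 lower in both against 1.32 and 17 opposite against 5.9. That r was 0.122 without UT-NTE1.25 replicate 2, 0.136 without NiW replicate 2, 0.146 without NiW-NTE1.25 replicate 1, and 0.359 over genes above 1 CPM in at least 2 libraries. Genes are not independent replicates, so no p-value belongs to these correlations. Within UT the doses correlated at r = 0.748, with 395 genes higher in both against 55.4 for independent lists and 73 lower in both against 11.2, and within NiW at r = 0.732, with 209 against 35.8 and 184 against 35.7. These pairs share their control libraries. For a simulation without change, the control and both nicotine groups were drawn anew around the control mean. The simulated pairs gave a mean r of 0.528 in UT and 0.593 in NiW, with 0 genes called in both in UT and at most 1 in NiW. The covariance was 0.27 against a simulated 0.0583 in UT and 0.165 against 0.0456 in NiW. With a separate control library for each comparison, a fit chosen after seeing the data, r was 0.41 and 0.4 in UT for the 2 ways to assign the libraries, with 233 higher in both against 17.5 and 180 against 18.4, and 0.334 and 0.312 in NiW, with 82 against 9.35 and 78 against 9.17. The covariance in that fit was 0.253 and 0.258 in UT and 0.143 and 0.14 in NiW, so it moved less than r. What both libraries of a control have in common stays shared in that fit.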

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

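Among the tests of this part, the corrections for GC content and the count of genes called after them were chosen only after the result was seen. The results of the next 2 paragraphs are differences in the response to nicotine between NiW and UT that passed the interaction test, given as the response in NiW minus that in UT on the log2 scale.

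At the lower dose 233 genes differed. By limma's camera with Benjamini-Hochberg adjustment the interferon-stimulated (adjusted p = 6.6e-07), interferon-gamma-induced (0.034), antigen presentation (0.014) and interferon signalling (0.031) lists responded more in NiW and the mesenchymal list (0.0011) less. The adjusted p was 0.7, 0.7, 0.7, 0.3 and 0.3 with an estimated correlation. The response was lower in NiW for CADM3 (-6.40) and ZNF804A (-4.05), whose values depend on the prior count, and for TMTC2 (-3.32), ROBO1 (-3.24), CELF2 (-3.12), FOSB (-3.10) and CCN2 (-1.28). It was higher for DHRS3 (1.34), C4B (1.06), C4A (1.04), DPYSL3 (1.03), TNFSF10 (0.94), GJA1 (0.91), C1S (0.47), C1R (0.44) and STAT2 (0.38). In CPM, CADM3 went from 14.5 to 24 in NiW and from 0 to 0.356 in UT, so its lower response holds on the log2 scale only.

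At the higher dose 2133 genes differed. By camera with Benjamini-Hochberg adjustment the antigen presentation (adjusted p = 8.2e-06) and interferon-gamma-induced (0.022) lists responded more in NiW, and the inflammatory (7.8e-06), cholesterol (7.8e-06), cell cycle (0.011) and endothelial (0.02) lists less. Their adjusted p with an estimated correlation was 0.43, 0.7, 0.18, 0.43, 0.43 and 0.43. The difference was -8.32 for CADM3 and -5.46 for ZNF804A, which depend on the prior count, -6.95 for ROBO1, -5.30 for LRCH2, -5.21 for TMTC2, -4.96 for SLC9A9, -2.66 for VWF, -2.61 for RSAD2, -1.64 for TIE1, -1.53 for GBP4, -1.11 for IFI44, -1.01 for CXCL8, -0.94 for HMGCS1, -0.91 for CXCL1, -0.51 for CDCA8, -0.47 for PLK1 and -0.27 for OAS3. On the other side it was 2.56 for TMSB15A, 2.07 for COLEC12, 2.01 for DHRS3, 1.98 for PCLO, 1.67 for GNG4, 1.48 for ANGPTL4, 0.93 for C1R, 0.87 for IFITM1, 0.43 for PSMB9, 0.42 for MX1 and 0.38 for B2M.

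Log2 fold changes at the higher dose rose with transcript GC content, with a Spearman correlation across genes of 0.473 in UT and 0.256 in NiW, and genes are not independent replicates. In NiW 89.4% of the calls were kept after a GC correction, and the median of the interferon-stimulated genes was 0.292 after it against 0.31 before, with 0.234 against 0.269 in UT, which argues against GC bias as the whole source of either. In UT 70.3% were kept, between the bounds of 50% and 80% set beforehand, so that test was undecided there. After the correction 5318 genes were called against 4806 before. That count includes genes not called before the correction, so it does not measure how far the earlier calls came from GC bias. The calls that were lost stay open. Depth stays open as a source of the trend. GC slopes differed between replicates by up to 0.0706 (NiW-NTE1.25, depths 1.31 times apart). This compares with 0.121 between UT-NTE2.5 and UT and 0.0835 between NiW-NTE2.5 and NiW. Slopes of the deeper minus the shallower library were 0.018 in NiW, 0.0706 in NiW-NTE1.25 and 0.0343 in NiW-NTE2.5. Where depths differed by over 1.5 times, in UT and UT-NTE2.5, this difference was -0.0478 and -0.0522, opposite in sign to the trend. In UT-NTE1.25, with depths 1.01 times apart, the difference was -0.0532, so replicates differed as much without a gap in depth. An effect of nicotine on GC-rich genes would look alike and was not tested.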

How the results depend on the processing

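The GC correction, the removal of pseudogene rows and arm medians, the minimum fold change and the separate control libraries were chosen after seeing the data. Total counts of called genes stayed within 1.5 times under DESeq2, RLE scaling, the stricter filter, a fit of the compared groups, the GC correction and without pseudogene rows. This holds for totals and not for each direction: after the GC correction the lower calls went from 119 to 200 in UT-NTE1.25, 1988 to 3255 in UT-NTE2.5, 235 to 384 in NiW-NTE1.25 and 1161 to 2149 for the dose in UT, and the higher calls from 40 to 75 and 766 to 1198 in the interactions. DESeq2 took the higher calls in NiW-NTE1.25 from 229 to 140, and the fit of the compared groups the lower calls in UT-NTE1.25 from 119 to 190. More genes were higher than lower in NiW against UT, UT-NTE2.5, NiW-NTE2.5 and both dose comparisons before the GC correction, and fewer after it. DESeq2 also turned this in NiW-NTE2.5 (2478 higher and 2839 lower) and for the dose in NiW (1686 and 1878). DESeq2 kept between 69% and 87.5% of the calls, RLE scaling 96.6% to 100% and the GC correction 70.3% to 99.1%. The order of comparisons below is NiW against UT, UT-NTE1.25, UT-NTE2.5, NiW-NTE1.25 and NiW-NTE2.5 against their controls, the interactions at 1.25 and 2.5 µM, and the dose in UT and in NiW. With an absolute log2 fold change of at least 1 the counts were 2033, 179, 844, 65, 825, 73, 360, 338 and 311, by construction lower, and most were higher calls: 1456, 175, 784, 58 and 680 in the first 5. Without a low-count filter the interaction at 1.25 µM had 367 calls against 233, and the cause was not tested.

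Leaving out 1 library in turn, where a lone library is assumed to vary like the other groups, gave counts from 222 to 437 for UT-NTE1.25, 2194 to 3783 for UT-NTE2.5, 180 to 368 for NiW-NTE1.25, 3967 to 5518 for NiW-NTE2.5, 84 to 196 and 1132 to 2043 for the interactions, and 1443 to 2124 and 2034 to 3643 for the doses. Fewer samples enter these fits.

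Of the lists, camera called 11, 9, 14, 12, 13, 5, 6, 16 and 9, and with an estimated correlation 0 in each comparison except 1 in NiW-NTE1.25. By fry for one direction 19 were called in NiW against UT, 5 in UT-NTE1.25, 4 in NiW-NTE1.25, 1 in the interaction at 1.25 µM and 15 for the dose in NiW, and by fry for either direction 29, 20, 28, 20, 29, 13, 26, 29 and 27. These test other questions than camera. Leaving out 1 library gave 3 to 8 lists in UT-NTE1.25, 7 to 14 in NiW-NTE1.25, 7 to 11 in NiW-NTE2.5 and 2 to 7 in the interaction at 1.25 µM.

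For the interferon-stimulated list the adjusted p with an estimated correlation was 0.27 in UT-NTE2.5, 0.43 in NiW-NTE1.25, 0.29 in NiW-NTE2.5 and 0.7 in the interaction at 1.25 µM. By fry for one direction it was 0.17 in NiW-NTE1.25 and 0.27 in that interaction, and for either direction 0.032 in UT-NTE1.25 and 6.7e-06 in the interaction at 2.5 µM. For antigen presentation it was 0.47, 0.22, 0.12 and 0.12 in the 4 nicotine comparisons and 0.7 and 0.43 in the interactions with an estimated correlation, and 0.073 in UT-NTE1.25 and 0.27 in the interaction at 1.25 µM by fry for one direction. Without 1 library the camera adjusted p of the interferon-stimulated list ranged from 0.018 to 0.7 in UT-NTE1.25 and from 0.0038 to 0.7 in the interaction at 2.5 µM, and that of antigen presentation from 0.014 to 0.056 in UT-NTE1.25 and from 0.013 to 0.13 in the interaction at 1.25 µM. The cause was not tested.

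The correlation between backgrounds was 0.359 at 1.25 µM and 0.577 at 2.5 µM over genes above 1 CPM in at least 2 libraries. Without 1 library it ranged from 0.122 to 0.184 and from 0.382 to 0.434, and that between doses from 0.564 to 0.834 in UT and from 0.545 to 0.832 in NiW. With a separate control library for each comparison the r between doses moved from 0.748 to 0.405 in UT and from 0.732 to 0.323 in NiW, and the cause was not tested. The covariance moved less, from 0.27 to 0.253 and 0.258 in UT, and from 0.165 to 0.143 and 0.14 in NiW. These fits covered 21823 genes in UT and 21896 in NiW, against 21177. Of 9558 alternative values for 737 named results 8983 stayed on the same side of the threshold. Another 469 fell short of it, most of them with 1 library left out, and 105 newly passed. Direction was compared only for results that had passed in the first place. Of their values 1 reversed, TYK2 in UT-NTE2.5, at -0.02 after the GC correction, where the cause was not tested.

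The labels do not say that replicate numbers pair the samples. Same-numbered deviations correlated between -0.061 and 0.031 over the 15 pairs of groups and all genes, and between -0.32 and 0.28 over abundant protein-coding genes. Among the latter, 3 pairs lay more than 0.1 above 0 and 3 pairs more than 0.1 below it. These values do not exclude a shared batch. A replicate block kept between 88.4% and 98.9% of the calls. Depth limits genes near 0, whose floor of 3 counts lay between 0.041 and 0.1 CPM.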

Other observations

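Chosen only after their results were seen were the tests of the nicotine groups, of shuffled positions and of DNA copy number for the chromosome arms, the rules and the tests of held-out reads, carry-over, other cell types, chance and chromosome for genes that appear, and the comparison of nicotine in UT with NiW.

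The higher dose was also set against the lower within each background, and the 4 genes named here were chosen after their values were seen. Antigen presentation genes were higher in 15 of 28 cases in UT (camera adjusted p = 8.79e-07, and 0.22 with an estimated correlation) and 20 in NiW (5.06e-13, and 0.15), 0 being lower, with HLA-B at 0.57 ± 0.04 in NiW. Cholesterol genes were higher in 20 of 26 cases with 0 lower in UT (4.49e-14, and 0.11 with an estimated correlation), with the feedback regulator INSIG1 at 1.10 ± 0.07, and in NiW 7 were higher and 3 lower, which was not called (0.225, and 0.63). Targets of p53 were higher in 7 of 24 cases in UT (0.000168, and 0.11 with an estimated correlation), and in NiW 8 were higher and 1 lower, which was not called (0.0809, and 0.32). Cell cycle genes were lower in 22 of 42 cases and higher in 1 in NiW (0.000346, and 0.26 with an estimated correlation), with the mitotic kinase AURKA at -0.41 ± 0.05, and lower in 4 and higher in 1 in UT, which was not called (0.191, and 0.5). Inflammatory genes were lower in 12 of 27 cases and higher in 3 in NiW (0.000346, and 0.16 with an estimated correlation), with CXCL8 at -0.67 ± 0.05, and higher in 4 and lower in 3 in UT, which was not called (0.543, and 0.66). Whether these dose steps differ between the backgrounds was not tested.

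Genes near 0 in both controls appeared with the higher dose, here in CPM of the library totals without scaling. Under a rule of less than 0.03 CPM in both controls and more than 0.3 CPM in an NTE2.5 group, 26 of 4353 genes did so, 12 in UT, 22 in NiW and 8 in both. CADPS2, a gene of regulated secretion, stood at 1.05 CPM in UT-NTE2.5 and 1.65 in NiW-NTE2.5, TMEM47 at 0.67 and 1.71, and FOLH1 at 0.326 and 0.831. The drug efflux pump ABCB1 reached 1.32 CPM and HLA-DRA 0.767 in NiW-NTE2.5. Both this rule, the first looked at, and a second were chosen after looking at the values. The second, with less than 0.05 CPM in both controls and at least 0.2 CPM in each library of an NTE2.5 group, gave 47 genes of 4819, 20 in UT, 39 in NiW and 12 in both.

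Genes called with nicotine in UT overlapped with those that differ between NiW and UT. At the higher dose log2 fold changes of the pair of comparisons correlated across genes at r = 0.514, with 1363 genes higher in both against 691 for independent lists, 932 lower in both against 467 and 907 opposite against 1150. At the lower dose r was 0.449, with 295 against 102, 60 against 28 and 71 against 127. Both comparisons share the UT libraries. For a simulation without change, UT and its nicotine groups were drawn anew around the UT mean. The simulated pairs gave a mean r of 0.521 at the higher and 0.499 at the lower dose, both above the observed values. NiW was simulated as unchanged too, so the simulated r lacks the real differences of NiW from UT. The simulated and observed r are therefore not alike, and this comparison does not decide how much overlap the shared libraries give. The covariance was 0.376 against a simulated 0.0559 at the higher dose and 0.238 against 0.0555 at the lower. With a separate control library for each comparison, a fit chosen after seeing the data, r was 0.34 and 0.367 at the higher dose, with 744 higher in both against 322 and 921 against 423, and 0.244 and 0.274 at the lower, with 124 against 40.1 and 179 against 50.1. The covariance in that fit was 0.364 and 0.373 at the higher dose and 0.215 and 0.219 at the lower, so it moved less than r. What both UT libraries have in common stays shared in that fit, and genes are not independent replicates. Of 4 genes under 0.03 CPM in UT and over 10 CPM in NiW, UT-NTE2.5 reached 13.2% of the NiW level for CADM3, 2.28% for RTN1, 2.11% for CPVL and 0.877% for SYK.

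Chromosome arms shifted as blocks between NiW and UT, with an SD of the arm medians of 0.229 on the log2 scale. After a GC correction the SD was 0.23, the medians at the nicotine doses correlated with it at r = 0.991 or more over the 41 arms, and 1000 shuffles of positions gave at most 0.0522, which argues against GC content, an oddity of the control libraries and changes unrelated to position. Over all 41 arms the medians of odd and of even bins of 10 Mb correlated at r = 0.96, so the shifts run along the arms. A candidate explanation is a difference in DNA copy number, which may have come with the nickel, the cloning or long culture, and these cannot be told apart by the design. No DNA was analysed here, and after removal of the arm medians 75.3% of the calls were kept.

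Deeper libraries alone would not give these genes at equal depth, yet 61.5% still met the rule after all libraries were thinned to the smallest total (74.5% under the second rule), between the bounds of 50% and 80% set beforehand, and of 32 pairs of gene and background picked on 0.5 of the reads 32 (100%, exact 95% interval 89.1 to 100) had both NTE2.5 libraries above both controls in the other reads thinned to equal totals, where chance gives 16.7%. That interval takes the pairs as independent, although they come from the same libraries. Carry-over between backgrounds was taken to leave the level in one under 0.1 of that in the other for at least 80% of the genes. This held for 8 of 26 (30.8%, exact 95% interval 14.3 to 51.8), while 57.7% lay within a factor of 5 (36.9 to 76.6, and 46.8% under the second rule). A different 8 genes, those that appear in both backgrounds, had over 0.3 CPM in each by the rule and at most 1.71 CPM. None of them could count as carry-over, so the 80% was out of reach and this comparison cannot decide on carry-over. Its intervals take genes as independent. Cells of the 5 types listed were taken to bring at least 50% of a marker list to 0.3 CPM or more and above its control level. At most 8.33% appeared, PDPN of 12 basal markers in UT-NTE2.5. Markers expressed in the controls, such as CD14 (6.7 CPM in UT-NTE2.5 against 7.78 in UT, and 19 against 12.5 in NiW) and COL1A1 (2670 against 2140, and 1740 against 1400), could hide a small share. A small share could also stay under the cut, so this test cannot exclude it, and other cell types were not tested. The 8 genes that appear in both backgrounds compare with 0.061 for independent lists (12 and 0.16 under the second rule), and 30.8% of the 26 lie on chromosome X against 6.73% of genes near 0 (Fisher's exact test, two-sided, p = 0.00021; 34% against 6.62%, p = 2.1e-08, under the second rule). Chromosome X was picked after the genes were seen, so these p-values make no allowance for other chromosomes. They also take genes as independent. No biological explanation was tested.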
